A study of Mus musculus with 3 samples.

How the data were processed

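Hippocampal cells of aged wild-type C57BL/6 mice were profiled in 3 libraries of the 10x Chromium 3′ chemistry. Per the labels' protocols, the tissue was digested with papain (about 20 units/ml), myelin was taken out with beads, and 10000 cells were aimed for. The labels give a single group of 2-year-old animals, so the libraries were treated as replicates 1, 2 and 3 of 1 group. The title of replicate 3 carries an age of 25 months while its age label equals that of the other two, so no age comparison was made. The series text names 6 hippocampi, and the labels do not say which animals went into which library.

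The deposited tables hold raw UMI counts (unique molecular identifiers) per gene and cell barcode. They were made by the authors with Cell Ranger against mm10, per the submitters' processing notes, and the version is not given in the sources used here. Every deposited barcode held at least 500 UMIs, and who set that minimum is not given either. Hyphens in gene names had been turned into dots, and 2448 of the 31053 symbols were restored. Of all symbols, 30463 were found in the GENCODE annotation of mm10, which gave identifiers and 1-based coordinates. Replicates 1, 2 and 3 held 45716237, 7185668 and 40377042 UMIs. Replicate 2, with 1062 barcodes, gave the widest intervals.

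Barcodes were kept with at least 500 UMIs, at least 300 genes and at most 20% mitochondrial UMIs, which left 6412, 954 and 5065 barcodes in replicates 1, 2 and 3. Scrublet, as held in scanpy 1.11.5 with an assumed doublet rate of 0.06, called 172, 9 and 166 doublets, which were removed. Counts were scaled to 10000 per cell, log-transformed, limited to 2000 variable genes and z-scored within each library (values limited to 10). Clusters were formed with 30 principal components, 15 neighbours and leidenalg 0.10.2 at resolution 1. Each cluster was named for the class with the best mean z-score among marker lists of 18 classes. A cluster stayed unnamed if fewer than 3 of its class's markers were detected in at least 20% of its cells, if its relative UMI count lay under 1 in 3 of the library's median with no marker among its 10 leading genes, or if those leading genes held more markers of another class. The last condition was relaxed after the clusters had been seen, to need at least 2 such markers. Unnamed clusters held 6.09%, 21.9% and 10.7% of the kept cells in replicates 1, 2 and 3 and took no part in the comparisons.

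UMIs were summed per library and class, with at least 20 cells in a library and at least 2 libraries per class. Astrocytes were compared with the unweighted mean of the other classes by edgeR's quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3). It used TMM scaling, filterByExpr, the library as a block and Benjamini-Hochberg adjustment at 0.05. The fold changes kept the test's default prior count. A prior count of 2 entered only the log CPM values that gave the sign in each library. For the astrocyte subclusters, each UMI was first assigned at random (probability 0.5, seed 1) to a clustering or a testing part, so that no UMI both formed and tested a subcluster. Clustering used 1500 variable genes without any gene of the fixed lists, 20 principal components and resolution 0.4. The testing part was summed per library and subcluster, with at least 10 cells in a library, and tested as the classes were, each subcluster against the unweighted mean of the others. All CPM values of subclusters come from the testing part.

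The 25 gene lists, fixed before the data were examined, were autophagy, lysosomal hydrolases, lysosomal membrane and v-ATPase, proteasome, ubiquitin conjugation and removal, cytosolic chaperones, ER chaperones and unfolded protein response, mTOR signalling, ER to Golgi secretory pathway, astrocyte-secreted synapse regulators, phagocytic receptors and adaptors, astrocyte homeostasis, pan-reactive astrocyte genes, neuroinflammation-type and injury-type reactive genes, lipid and cholesterol synthesis, glycolysis, nuclear genes of oxidative phosphorylation, mitochondrially encoded genes, ribosomal proteins, interferon response, MHC class I, disease-associated microglia genes, cell cycle arrest and senescence, and dissociation and immediate early genes. Some genes stand in more than 1 list. Lists were tested with camera at a preset inter-gene correlation of 0.01, with an estimated correlation and fry beside it, adjusted over all lists of a comparison family. Marker genes were taken out of the lists in the class comparison, since they had named the classes. In the subclusters the marker lists themselves were tested the same way, as a measure of RNA of other cells. The disease-associated microglia list holds Apoe, which astrocytes also make.

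Genes were named by a rule written before the data were examined. It took the 8 highest and the 8 lowest log2 changes among genes past the threshold with 1 sign in every library and at least 20 CPM on one side, leaving out predicted gene models, and in the class comparison the markers. It added the members with the smallest p of each called list, and Gfap, Sqstm1, Map1lc3b, Lamp1, Lamp2, Ctsd and Mtor in every comparison. Of the list members, only the one with the smallest p in the list's own direction was kept for the text; this narrowing was made after the values and their alternatives had been seen. Where a subcluster had no UMI of a gene, the fold is a bound from a floor of 3 UMIs over the whole subcluster. Shares of cells carry exact (Clopper-Pearson) 95% binomial intervals. No test was run on the shares.

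The tests were tested on simulated counts drawn from the real means and library sizes with 200 changed genes. In the class comparison, 30%, 74.6% and 93.7% of the genes changed 1.5, 2 and 4 fold were recovered, with 17 false calls among 147. In subclusters 1, 2, 3 and 4, genes changed 2 fold were recovered in 61.5%, 44.1%, 75% and 38.2% of cases and genes changed 4 fold in 93.4%, 73.5%, 97% and 86.1%, with 2 to 4 false calls each and no wrong sign. Clustering of simulated cells without any subclusters, followed by the same edgeR test, called 0 of 6855 genes with disjoint UMIs (279 at an unadjusted p under 0.05) and 0 of 8721 with all UMIs used for both (353 at an unadjusted p under 0.05).

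Alternatives fixed before the data were examined were RLE in place of TMM, DESeq2 1.42.0, no low-count filter, no replicate block, each replicate left out, a stricter cell filter (at least 1000 UMIs, 500 genes, at most 10% mitochondrial UMIs), doublets kept, all UMIs for both steps, list genes kept in clustering, resolutions of 0.2 and 0.8, z-scores over all libraries, a second random assignment of UMIs (seed 2) and camera with an estimated correlation. Chosen after seeing the data were cells with at least 2000 UMIs and the erythrocyte class left out, for the classes, and cells with 2000 to 20000 UMIs and subcluster 4 left out of the fit, for the subclusters. Subclusters of an alternative were matched to those reported by their shared cells, with a Jaccard index of at least 0.2. The remaining steps ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9 and matplotlib 3.10.9. Raw reads were not used here.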

Results

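RNA of single cells was counted in the hippocampus of old wild-type mice in 3 libraries, replicates 1, 2 and 3 of a single group. Replicates 1, 2 and 3 held 7241, 1062 and 6456 barcodes with 45716237, 7185668 and 40377042 UMIs. The median barcode held 5075, 3782 and 4550 UMIs in replicates 1, 2 and 3, and its mitochondrial share was 3.16%, 4.48% and 6.05%. Haemoglobin RNA, which red blood cells make, took 0.749%, 2.01% and 1.23% of all UMIs, and 37.5%, 86.2% and 84.8% of barcodes held at least 1 UMI of a beta-globin gene. After filtering, 6240, 945 and 4899 cells were kept. The series title concerns astrocytes and protein homeostasis, so the comparisons asked how RNA of the protein quality control machinery differed between astrocytes and other cells, and between groups of astrocytes. There were no young samples or any other group to compare with, so nothing here compares ages. The edgeR p-values rest on how far differences between profiles varied over these 3 libraries, pooled over all classes or all subclusters. The camera p-values set a list against the other genes at the preset or estimated correlation. The labels do not tie libraries to animals, so neither measures a spread between animals. The intervals and floors cover counting error only.

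Endothelial cells, which line the blood vessels, were the most numerous class, with 4235 cells and 34.9% ± 1.42 (SD, n = 3) of the kept cells. Astrocytes numbered 2622 and made up 19.3% ± 6.00 (SD, n = 3). Their share was 25.8% (exact 95% interval 24.8 to 26.9) in replicate 1, 14.1% (11.9 to 16.5) in replicate 2 and 17.9% (16.8 to 19.0) in replicate 3, so the libraries differed by more than counting error. Microglia, the resident immune cells of the brain, followed with 1855 cells and 14.9% ± 1.56, and ciliated ependymal cells with 1065 cells and 8.04% ± 4.44. The ependymal share was 13.1% in replicate 3 and 6.01% and 4.97% in replicates 1 and 2. Pericytes, which wrap capillaries, made up 2.52% ± 0.655, oligodendrocyte precursors (OPC) 2.44% ± 0.551, border macrophages 1.63% ± 0.665 and erythrocytes 1.59% ± 0.638 (SD, n = 3 each). The erythrocyte cluster had a median of 11953 UMIs, and all 10 endothelial markers were detected in it. Only 32 neurons, 37 oligodendrocytes, 52 fibroblasts, 81 smooth muscle cells and 20 B cells were found, and no oligodendrocyte among the 945 cells of replicate 2 (exact 95% upper bound 0.390%). Unnamed clusters held 12.9% ± 8.13 of the cells, or 8.39% without replicate 2. With the stricter cell filter 804 astrocytes were left and their share came to 7.84%. The filter's limit of 10% mitochondrial UMIs lay near the medians of the large astrocyte clusters, 10.74%, 9.79% and 10.6%. The largest endothelial cluster had a median of 2.91%. A cluster of 205 cells closest to astrocytes also stayed unnamed under that filter.

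**Figure D1:**
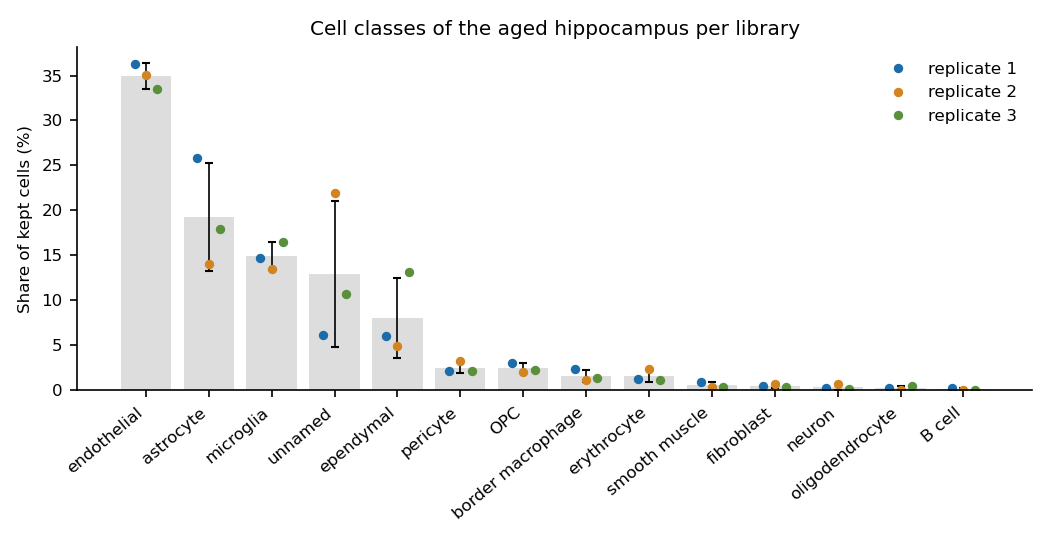
Share of kept cells (vertical axis, percent) for each named class and the unnamed clusters (horizontal axis), with bars for the mean over 3 libraries, error bars for the SD and 1 point per library. Endothelial shares lie between 33.5% and 36.3%, while astrocyte shares lie between 14.1% and 25.8%.

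Astrocytes were compared with the mean of the other classes, and Slc4a4 and Gfap were higher and Hspa1b lower in them. Slc4a4, a sodium bicarbonate cotransporter (ENSMUSG00000060961.14, chromosome 5, 88886818 to 89239653 on mm10), stood at 1220 ± 276 CPM (SD, n = 3) in astrocytes and 33.7 CPM in the other classes. It was among the 10 leading genes of an astrocyte cluster. Gfap, the intermediate filament of astrocytes (ENSMUSG00000020932.14, chromosome 11, 102887336 to 102900912), stood at 2024 ± 961 CPM against 222 CPM. Hspa1b, a stress-inducible Hsp70 (ENSMUSG00000090877.3, chromosome 17, 34956436 to 34959238), stood at only 73.0 ± 36.5 CPM against 2762 CPM. Of the genes outside the marker lists, the largest rises were those of Aspg (7.88 ± 0.38, log2 ± SE), Acat3 (7.70), the transcription factor Fezf2 (7.23), Ranbp3l (7.15), Myoc (7.13), the secreted thrombospondin Thbs4 (7.11), Disp3 (6.86) and Ppp1r3g, a subunit that targets phosphatase to glycogen (6.77). The largest falls included Pmaip1, a proapoptotic p53 target (-5.32 ± 0.52), Enc1 (-5.14), Rassf4 (-5.10), the cholesterol exporter Abcg1 (-5.03) and the thrombin receptor Thbd (-4.96). In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 4497 of 13028 genes were higher and 3066 lower in astrocytes (22 summed profiles of 8 classes), with adjusted p between 1.97e-18 for Thbs4 and 5.83e-06 for Hlx, a homeobox factor with a change of -4.97, among the genes named by size, all of them in 3 of 3 libraries. Without replicate 1, 3250 genes were higher and 1897 lower, and Thbd and Hlx, with 6 and 4 UMIs in all astrocytes, lost their calls (adjusted p = 1.0 for both), as did Filip1 (-5.16 with all libraries, -3.87 and adjusted p = 1.0 without replicate 1).

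Among the groups that were higher, all 16 tested members of the astrocyte homeostasis list rose, with a median of 4.23 (log2), and 26 of the 30 lipid and cholesterol synthesis genes rose while 2 fell (median 1.99). Scd2, which desaturates stearate, changed by 3.86 ± 0.13 to 1745 ± 281 CPM. Of the 18 tested synapse regulators secreted by astrocytes, 14 rose and 1 fell (median 3.04), led by the glypican Gpc5 at 5.24 ± 0.17. For energy metabolism, 60 of the 70 nuclear genes of oxidative phosphorylation rose and 1 fell (median 0.70), all 13 mitochondrially encoded genes rose (median 1.40), and 12 of 19 glycolysis genes rose while 3 fell (median 0.85). Ndufc2 of complex I changed by 1.88, mt-Nd4 by 1.76 to 9123 ± 981 CPM, and the lactate dehydrogenase subunit Ldhb by 3.30. Counts adjusted over the list alone were the same for these 6 lists. With camera the adjusted p was 7.75e-13 for homeostasis, 1.42e-08 for lipid synthesis, 1.64e-05 for synapse regulators, 7.75e-10 for oxidative phosphorylation, 9.12e-06 for mitochondrially encoded genes and 0.0135 for glycolysis. With an estimated correlation none of the 6 held: adjusted p = 0.22 for homeostasis and lipid synthesis. It was 0.275, 0.328, 0.329 and 0.409 for the rest in that order.

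Among the groups that were lower, all 78 ribosomal protein genes fell (median -1.20), Rpl10 by 1.74 on the log2 scale. All 26 dissociation and immediate early genes fell (median -2.81), among them Zfp36, which destabilises inflammatory mRNAs (-3.30 ± 0.27), and all 12 MHC class I genes fell (median -1.85), H2-Q4 by 2.89 on the log2 scale. Of the 24 interferon response genes 16 fell and 2 rose (median -1.15), Irf7 by 2.30 on the log2 scale, and of the 19 genes of cell cycle arrest and senescence 11 fell and 1 rose (median -0.82), the p53 target Bbc3 by 2.66. With camera the adjusted p was 8.51e-34 for ribosomal proteins, 2.95e-14 for immediate early genes, 1.01e-05 for MHC class I, 0.000756 for interferon response and 0.00163 for senescence. With an estimated correlation none of these held: adjusted p = 0.275 for the first pair, and 0.298, 0.409 and 0.298 for the rest. Adjusted over the list alone, 17 interferon genes fell and the other counts were the same.

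The protein quality control lists were lower or divided in astrocytes. Of 37 cytosolic chaperone genes 25 fell and 4 rose (median -0.58), Hspa1b by 4.47 on the log2 scale. Of 35 genes for ER chaperones and the unfolded protein response 23 fell and 5 rose (median -0.64), Ppp1r15a, which restores translation after stress, by 3.18. Of 36 genes for ubiquitin conjugation and removal 12 fell and 3 rose (median -0.17). Of 46 genes of the ER to Golgi secretory pathway 15 fell and 4 rose (median -0.12), Arf1 by 1.14. Of 38 proteasome genes 7 fell and none rose in the same edgeR test (median -0.11), the lid subunit Sem1 by 1.11 to 153.0 ± 20.1 CPM against 345.8 CPM. Adjusted over the list alone, ubiquitin had 11 lower and 1 higher, the secretory pathway 14 and 4 and the proteasome 2 and 0. The first pair was unchanged. By camera the adjusted p was 9.12e-06, 8.93e-05, 0.00409, 0.0253 and 0.0282 in the same order, and adjusted p = 0.298, 0.298, 0.359, 0.418 and 0.527 with an estimated correlation. Without replicate 1 the proteasome call was lost (adjusted p = 0.0693), and with the stricter cell filter its median was 0.065 (adjusted p = 0.342). The degradative lists were not called by camera, while fry, which does not compare a list with other genes, gave an adjusted p of 3.87e-06 for the lysosomal membrane and 0.00315 for mTOR, and 0.115 for the proteasome that camera called. Of 48 autophagy genes 9 rose and 13 fell (8 and 13 adjusted over the list alone), with a median of 0.19 and a mean of 0.03 but a downward test (adjusted p = 0.397). Of 48 lysosomal hydrolases 11 rose and 18 fell (the same adjusted over the list alone, median -0.22, adjusted p = 0.107). Of 37 genes for the lysosomal membrane and v-ATPase 16 rose and 3 fell (the same, median 0.24, adjusted p = 0.480). Of 36 mTOR signalling genes 15 rose and 8 fell (the same), with a median of 0.15 and a mean of 0.26 against a downward test (adjusted p = 0.810).

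The named degradative genes moved by less than those of the leading groups. Lamp1, a lysosomal membrane protein, was higher by 0.50 ± 0.14 (log2 ± SE) and Lamp2 had a fitted change of 0.36 ± 0.14, the lysosomal protease Ctsd was lower at -0.44 ± 0.18 and the autophagy receptor Sqstm1 lower at -0.96 ± 0.30, each in 3 of 3 libraries. The kinase Mtor was higher by 0.63 ± 0.20 in 2 of 3 libraries, and Map1lc3b, which coats autophagosomes, had a change of 0.22 ± 0.14 that did not pass. The mean CPM of Lamp2 was 199.6 in astrocytes and 206.6 in the other classes, the opposite order to its fitted change. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the adjusted p was 0.00232 for Lamp1, 0.0323 for Lamp2, 0.0378 for Ctsd, 0.00737 for Sqstm1, 0.00978 for Mtor and 0.165 for Map1lc3b. Leaving out a replicate ended the calls of Lamp2 (adjusted p = 0.418, 0.0779 and 0.165 without replicates 1, 2 and 3), of Ctsd (0.0716 without replicate 1 and 0.138 without replicate 3), of Mtor (0.0809 without replicate 1 and 0.0524 without replicate 2), and of Sqstm1 and Lamp1 without replicate 2 (0.0511 and 0.0679).

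Lists tied to reactive states and phagocytosis were not called by camera against the other classes. Fry passed them, with an adjusted p of 0.00017 for pan-reactive, 6.12e-09 for phagocytic, 0.0362 for neuroinflammation-type, 0.0249 for injury-type and 0.0316 for disease-associated microglia genes. Of 12 pan-reactive astrocyte genes 8 rose and 1 fell (8 and 2 adjusted over the list alone, median 2.03, adjusted p = 0.214). Of 20 phagocytic receptors and adaptors 12 rose and 4 fell (the same, median 1.24, adjusted p = 0.0698). Of 12 neuroinflammation-type genes 3 rose and 5 fell (4 and 6, median -0.85, adjusted p = 0.101). Of 8 injury-type genes 2 rose and 4 fell (3 and 4, median -0.65, adjusted p = 0.194). Of 19 disease-associated microglia genes 6 rose and 7 fell (the same, median -0.72, adjusted p = 0.810). As levels, proteasome RNA took 0.352% ± 0.0414 (SD, n = 3) of astrocyte UMIs, against 0.352% in microglia, 0.481% in endothelial cells and 0.534% in OPC. Cytosolic chaperones took 0.437% ± 0.0206 of astrocyte UMIs and 3.36% ± 0.594 of endothelial UMIs, and lysosomal hydrolases 0.515% ± 0.0200 against 3.601% ± 0.513 in microglia. Autophagy RNA took 0.258% ± 0.0219 in astrocytes and 0.365% in ependymal cells. Mitochondrially encoded RNA took 11.1% ± 0.852 in astrocytes and 3.73% in endothelial cells, and ribosomal protein RNA 4.03% ± 0.459 against 16.7% ± 0.488 in microglia.

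Within the astrocytes, clustering without any list gene gave 5 subclusters of 948, 860, 741, 55 and 18 cells. Subcluster 1 held 34.7% ± 2.63 (SD, n = 3) of the astrocytes of a library, subcluster 2 held 35.6% ± 6.36 and subcluster 3 held 26.6% ± 3.54. Subcluster 4 came from 15 cells of replicate 1 and 40 of replicate 3, with none among the 133 astrocytes of replicate 2, and held 0.931% and 4.56% of the astrocytes of those libraries. Subcluster 5 had 4, 3 and 11 cells and was too small to test. The subclusters differed in depth, with medians of 3066.5, 959.5, 9698 and 20275 UMIs per cell in subclusters 1, 2, 3 and 4, and less in mitochondrial share, with medians of 11.7%, 9.91%, 10.05% and 8.66%. All 4 were tested in 1 fit of 6829 genes over 11 summed profiles with 5 residual degrees of freedom. A scaling change moved the median of all genes in subcluster 1 from -0.02 to 0.11 with RLE and to 0.12 with DESeq2, so its balance of higher and lower genes depends on the scaling.

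**Figure D2:**
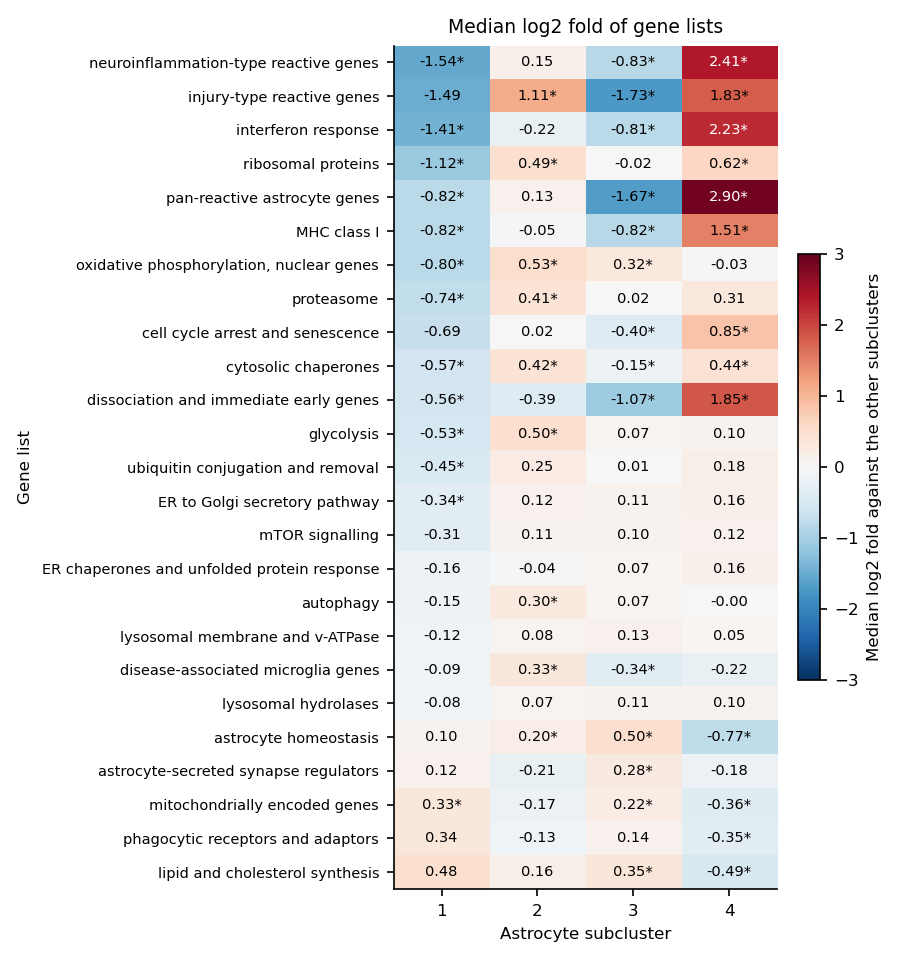
Median log2 fold of each gene list (vertical axis) in astrocyte subclusters 1 to 4 (horizontal axis) against the unweighted mean of the other subclusters, coloured from blue (lower) to red (higher), with a star where camera at the preset correlation passed the threshold. Proteasome, respiratory and ribosomal lists are lowest in subcluster 1 (-0.74, -0.80 and -1.12), and the pan-reactive and interferon lists are highest in subcluster 4 (2.90 and 2.24).

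Subcluster 1 had more RNA of Gria2 and less of Vim and Gfap than the other astrocytes. Gria2, an AMPA receptor subunit (ENSMUSG00000033981.14, chromosome 3, 80681450 to 80802835), stood at 1459 ± 507 CPM (SD, n = 3) against 238 CPM. Among the 8 largest rises were those of Spaca6 (3.75 ± 0.54, log2 ± SE), the potassium channel Kcnt1 (3.55), the transcriptional regulator Rai1 (3.41), the histamine receptor Hrh1 (3.16), Gria2 (3.04 ± 0.19), the metalloprotease Adamts9 (2.66) and the DNA demethylase Tet2 (2.56 ± 0.31). Among the 8 largest falls were those of Myoc (-4.14 ± 0.58), the ion pump regulator Fxyd6 (-3.01), the chemokines Cxcl1 (-2.82) and Cxcl5 (-2.19), Igfbp7 (-2.24) and the intermediate filament Vim (-2.15 ± 0.23). Gfap was lower too, at -1.32 ± 0.20 and 1222 ± 453 CPM against 3308 CPM. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1502 genes were higher and 1461 lower (adjusted p between 4.30e-28 for Gria2 and 4.88e-05 for Hrh1 and 8.21e-05 for Cxcl1 among these, each in 3 of 3 libraries). The counts were 1793 and 1139 with RLE, 1277 and 734 with DESeq2, 753 and 574 without replicate 1, and 682 and 558 without replicate 3. Myoc, Fxyd6 and Cxcl1 lost their calls without replicate 1 (adjusted p = 0.994, 1.0 and 0.106), and Igfbp7 without replicate 3 (-0.90, adjusted p = 0.260), while Cxcl5 turned to 0.46 with the stricter cell filter.

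The proteasome list was lower in subcluster 1, with 22 of 37 tested genes lower, 27 adjusted over the list alone, and none higher in the same edgeR test (median -0.74). Pomp, the proteasome maturation protein (ENSMUSG00000029649.10, chromosome 5, 147860461 to 147876456), fell by 1.26 on the log2 scale to 87.8 ± 35.0 CPM against 218.4 CPM. All 78 ribosomal protein genes (median -1.12) and all 70 nuclear genes of oxidative phosphorylation (median -0.80) were lower, also adjusted over the list alone, with Rps3a1 at -1.36 ± 0.18 and Atp5e at -1.14 ± 0.18. Of 37 cytosolic chaperones 22 fell and 2 rose (22 and 3 adjusted over the list alone, median -0.57), the small heat shock protein Cryab to 111 ± 73.8 CPM against 384 CPM. Of 18 glycolysis genes 12 fell and 2 rose (13 and 2, median -0.53), Aldoa by 1.03. Of 33 ubiquitin genes 15 fell and 4 rose (16 and 4, median -0.45), led by Rps27a, which encodes a ribosomal protein fused to ubiquitin (-1.17). Of 42 secretory pathway genes 16 fell and 2 rose (the same, median -0.34), Sec61g by 0.99. From camera the adjusted p was 7.02e-08 for the proteasome, 1.23e-43 for ribosomal proteins, 3.23e-22 for oxidative phosphorylation, 0.000101 for chaperones, 0.000434 for glycolysis, 0.0153 for ubiquitin and 0.0126 for the secretory pathway. With an estimated correlation none held: adjusted p = 0.288, 0.128, 0.264, 0.264, 0.264, 0.337 and 0.463, in that order. Among cells of 2000 to 20000 UMIs the proteasome median was -0.461 (adjusted p = 0.00164). That restriction ended the calls of glycolysis, ubiquitin and the secretory pathway (adjusted p = 0.117, 0.182 and 0.273), as did leaving out replicate 3 for ubiquitin (0.114) and leaving out subcluster 4 for ubiquitin and the secretory pathway (0.0878 and 0.0506). At resolution 0.2 the oxidative phosphorylation median was -0.096 (adjusted p = 0.0533).

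In contrast to the nuclear respiratory genes, 4 of the 13 mitochondrially encoded genes were higher and none lower in subcluster 1, also adjusted over the list alone (edgeR, median 0.33, camera adjusted p = 0.0242, and adjusted p = 0.708 with an estimated correlation), with mt-Nd6 at 0.77 ± 0.20. The call of mt-Nd6 was lost without replicate 3 (0.50, adjusted p = 0.279). Lists of reactive states were lower. Of 12 pan-reactive genes 7 fell and 1 rose (8 and 1 adjusted over the list alone, median -0.82). Of 10 neuroinflammation-type genes 7 fell and 2 rose (the same, median -1.54). Of 21 interferon genes 13 fell and none rose (14 adjusted over the list alone, median -1.41), 5 of 10 MHC class I genes fell (the same, median -0.82), and 12 of 24 immediate early genes fell (14 adjusted over the list alone, median -0.56). Lcn2, an iron-binding acute phase protein, was at -4.73 ± 0.40, complement C3 at -2.74 and Ifitm3 at -1.89, each in 2 of 3 libraries, and B2m at -1.25 and the NF-kB inhibitor Nfkbia at -0.93, each in 3 of 3. Camera gave an adjusted p of 0.0018, 0.0121, 0.00371, 0.0105 and 0.00475 in the order of these lists, and adjusted p = 0.347, 0.359, 0.506, 0.347 and 0.592 with an estimated correlation. These values rest in part on subcluster 4. With it left out of the fit, the adjusted p was 0.369, 0.417, 0.472 and 0.328 for the first 4, and the immediate early median turned to 0.215 (adjusted p = 0.212). It also turned with all UMIs for clustering and testing (0.335) and at Leiden resolution 0.8 (0.302). Without replicate 3, Lcn2 (adjusted p = 0.214), C3 (0.988) and the neuroinflammation, interferon and MHC lists (0.358, 0.517 and 0.0943) lost their calls, and the immediate early list lost its call without replicate 1 (0.105). Among cells of 2000 to 20000 UMIs the MHC and immediate early lists lost theirs (0.134 and 0.115). With fry the pan-reactive (adjusted p = 0.0912), neuroinflammation-type (0.0767), mitochondrial (0.144), interferon (0.154) and immediate early lists (0.173) did not pass.

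Lists for degradation by other routes were not called by camera in subcluster 1, though autophagy passed with fry (adjusted p = 0.0108). Of 30 autophagy genes 10 fell and 3 rose (the same adjusted over the list alone, median -0.15, adjusted p = 0.0958), among the first Sqstm1 at -1.13 ± 0.18 and Map1lc3b at -0.76 ± 0.18. Of 34 lysosomal hydrolases 6 fell and 1 rose (6 and 0 adjusted over the list alone, adjusted p = 0.2998). Of 30 lysosomal membrane genes 8 fell and 4 rose (the same, adjusted p = 0.217), with Lamp1 at -0.66 ± 0.17, Lamp2 at 0.02 ± 0.17 and Ctsd at -0.30 ± 0.17, the last pair not called. Of 31 mTOR signalling genes 9 rose and 8 fell (the same), with a median of -0.31 and a mean of 0.04 (adjusted p = 0.526), and Mtor was higher by 1.12 ± 0.36 in 2 of 3 libraries. Of 26 ER chaperone genes 5 fell and 1 rose (4 and 0 adjusted over the list alone, adjusted p = 0.307). Under edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the adjusted p was 1.65e-07 for Sqstm1, 0.000252 for Map1lc3b, 0.00105 for Lamp1, 0.00692 for Mtor, 0.933 for Lamp2 and 0.154 for Ctsd, and Lamp1 lost its call without replicate 1 (-0.54, adjusted p = 0.120). The remaining lists were not called by camera: 5 of 16 synapse regulators rose and 2 fell (adjusted p = 0.827), 6 of 16 phagocytic genes rose and 1 fell (0.0833), 9 of 24 homeostasis genes rose and 7 fell (0.664), 11 of 28 lipid genes rose and 3 fell (0.123), 2 of 12 disease-associated microglia genes rose and 4 fell (0.523), 4 of 10 senescence genes fell and 1 rose (0.0850) and 2 of 4 injury-type genes fell (0.0699), with the same counts adjusted over the list alone. Fry passed the phagocytic, senescence and injury-type lists (adjusted p = 0.0204, 0.0277 and 0.0239). Camera called no marker list of another class in subcluster 1, while fry passed the microglial (0.0126) and endothelial markers (0.0257). There 3 of 6 microglial markers were higher (median 0.71, adjusted p = 0.0859) and 1 of 7 endothelial markers (median 0.80, adjusted p = 0.119). Astrocyte (0.349), oligodendrocyte (0.384), pericyte (0.384), erythrocyte (0.383) and smooth muscle markers (0.938, median 0.44 with a downward test) were not called by either tool.

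In subcluster 2 the largest rises were those of haemoglobin genes. Hbb-bt, a beta-globin (ENSMUSG00000073940.3, chromosome 7, 103812524 to 103813996), was higher by 6.48 ± 0.29 (log2 ± SE), at 1381 ± 2021 CPM (SD, n = 3) against 27.2 CPM. It stood at 35.9, 400.9 and 3705 CPM in replicates 1, 2 and 3, and 5 cells of replicate 3 held 90.5% of the haemoglobin UMIs of subcluster 2 there. Hba-a2, Hbb-bs and Hba-a1 were higher by 4.68, 4.48 and 4.44. Ctla2a (4.06), the smooth muscle actin Acta2 (3.93), the myeloid transcription factor Spi1 (3.92) and the vascular gene Apold1 (3.83) followed. Rai1 and Spaca6 had no UMI in subcluster 2 and were at least 6.35-fold and 5.78-fold lower, and the falls of Tet2, Letm2, Zbtb37 and Ttll3 rested on 1 or 2 UMIs each. Using edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 513 genes were higher and 447 lower (adjusted p between 2.92e-39 for Hbb-bt and 0.00461 for Spi1 among the rises, all in 3 of 3 libraries). The counts were 377 and 581 with RLE, 220 and 300 with DESeq2, 51 and 89 without replicate 1 and 57 and 141 without replicate 3. Ctla2a and Apold1 lost their calls without replicate 1 (adjusted p = 0.0757 and 0.445) and Acta2 without replicate 3 (0.243). The marker lists of other classes moved with this subcluster: all 4 erythrocyte markers (median 4.58, adjusted p = 2.41e-35, and adjusted p = 0.0230 with an estimated correlation), 4 of 6 microglial markers (5 adjusted over the list alone, 2.32, 6.34e-13, and adjusted p = 0.0230 with an estimated correlation) and 5 of 7 endothelial markers (6 adjusted over the list alone, 2.02, 5.08e-07, and adjusted p = 0.0486 with an estimated correlation) were higher. Of 3 smooth muscle markers 1 was higher (3 adjusted over the list alone, median 1.42, adjusted p = 0.00565, and adjusted p = 0.224 with an estimated correlation). Astrocyte markers also rose (2 of 14, 3 adjusted over the list alone, median 0.20, adjusted p = 0.0404, and adjusted p = 0.564 with an estimated correlation), while oligodendrocyte (adjusted p = 0.103) and pericyte markers (0.453) were not called.

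Within the fixed lists, 41 of 78 ribosomal protein genes rose in subcluster 2 (68 adjusted over the list alone, median 0.49), 37 of 70 oxidative phosphorylation genes (57, median 0.53), 9 of 18 glycolysis genes (10, median 0.50), 10 of 37 cytosolic chaperones (10, median 0.42), 6 of 37 proteasome genes (6, median 0.41) and 7 of 30 autophagy genes (8, median 0.30), with none lower in the edgeR test. Aldoc, a brain aldolase, changed by 0.93 ± 0.16 to 8938 ± 1929 CPM, the small heat shock protein Hspb1 by 1.60, the proteasome subunit Psma6 by 0.75, Uqcrfs1 of complex III by 0.88, Rpl29 by 0.89 and Rab7, which guides late endosomes, by 0.87. Of 12 disease-associated microglia genes 5 rose and 1 fell (the same adjusted over the list alone, median 0.33), led by the chemokine Ccl4 at 2.63 ± 0.19. Of 4 injury-type genes 2 rose (median 1.11), with the monocyte receptor Cd14 at 1.73. Hspb1 was among the 10 leading genes of an endothelial cluster, and Ccl4 and Cd14 among those of microglial clusters. Whether these rises and those of the lists came from RNA of other cells, whose markers also rose in subcluster 2, was not tested. The compared mean includes subcluster 1, low in ribosomal, respiratory and proteasome RNA. Of 24 homeostasis genes 4 rose and 2 fell (the same, median 0.20). The adjusted p in camera was 1.91e-20 for ribosomal proteins, 2.2e-18 for oxidative phosphorylation, 0.000117 for glycolysis, 0.000434 for chaperones, 8.23e-05 for the proteasome, 0.0458 for autophagy, 3.89e-07 for the microglia list, 0.0205 for the injury list and 0.0353 for homeostasis. With an estimated correlation none held: adjusted p = 0.299, 0.299, 0.273, 0.327, 0.273, 0.263, 0.154, 0.327 and 0.728, in that order. The autophagy call was lost without any single replicate (adjusted p = 0.199, 0.165 and 0.0701 without replicates 1, 2 and 3), the chaperone call without replicate 3 (0.135), the injury call without replicates 2 and 3 (0.167 and 0.316) and the homeostasis call without replicate 1 (0.562). The homeostasis median turned to -0.18 with subcluster 4 left out, to -0.291 with the stricter cell filter (adjusted p = 0.00367) and to -0.021 at Leiden resolution 0.8. Lowest medians over alternatives with all replicates were -0.598 for the injury list, -0.224 for autophagy, -0.049 for the microglia list and -0.022 for chaperones. Ccl4 turned to -0.034 with doublets kept.

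Of the genes followed in every comparison, Sqstm1 (0.59 ± 0.19), Map1lc3b (0.57 ± 0.18) and Ctsd (0.54 ± 0.18) were higher in subcluster 2 in 3 of 3 libraries, while Gfap (0.21), Lamp1 (0.34), Lamp2 (-0.48) and Mtor (-1.10) did not pass. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the adjusted p was 0.0256, 0.0226 and 0.0286 for the first 3, and each call was lost without replicate 1 (0.599, 0.368 and 0.271) and without replicate 3 (0.257, 0.569 and 0.683). Ctsd turned to -0.504 with doublets kept (adjusted p = 0.0143), to -0.011 with the stricter cell filter and to -0.103 among cells of 2000 to 20000 UMIs. The list genes Rab7 (0.073 and 0.318), Psma6 (0.513 and 0.104) and Rpl29 (0.0684 and 0.0832) also lost their calls without replicate 1 and without replicate 3, Uqcrfs1 (0.315) without replicate 1, and Aldoc (0.0798) and Cd14 (0.181) without replicate 3. With fry the chaperone (adjusted p = 0.0695), homeostasis (0.275) and injury lists (0.0513) and the astrocyte (0.229) and erythrocyte markers (0.0531) did not pass. Further lists were not called by camera or fry in subcluster 2. The members higher and lower over all genes, and then adjusted over the list alone, were 4 and 0 (3 and 0) of 34 for lysosomal hydrolases (adjusted p = 0.0771). They were 3 and 0 (the same) of 30 for the lysosomal membrane and v-ATPase (0.706, median 0.08 against a mean of -0.05) and 3 and 1 (5 and 1) of 33 for ubiquitin (0.0699). For mTOR they were 3 and 3 (4 and 3) of 31 (0.749, median 0.11 against a mean of -0.12), for synapse regulators 1 and 1 (1 and 2) of 16 (0.710) and for phagocytic genes 1 and 1 (the same) of 16 (0.602). For pan-reactive genes they were 2 and 1 (the same) of 12 (0.670), for neuroinflammation-type genes 1 and 0 (the same) of 10 (0.836) and for lipid synthesis 3 and 2 (4 and 4) of 28 (0.620). For interferon they were 0 and 2 (0 and 1) of 21 (0.193), for MHC class I 1 and 0 (the same) of 10 (0.946, median -0.05 with an upward test) and for immediate early genes 2 and 4 (2 and 7) of 24 (0.111). No member of the ER chaperone (26 genes, adjusted p = 0.670), secretory (42, 0.662), mitochondrially encoded (13, median -0.17, 0.0741) or senescence lists (10, median 0.02 against a mean of -0.06, 0.985) passed edgeR's test, in which 1933 of all genes had an unadjusted p under 0.05.

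Subcluster 3, the deepest of the 3 large groups, had more RNA of Hsd11b1 and Nnat and less of Ccl2, relative to a mean that includes the small subcluster 4. Hsd11b1, which activates glucocorticoids (ENSMUSG00000016194.14, chromosome 1, 193221634 to 193264075), was higher by 1.45 ± 0.20 (log2 ± SE), at 362 ± 51.6 CPM (SD, n = 3) against 215 CPM. Further rises were those of Hrh1 (2.63), the alarmin Il33 (1.31), the imprinted gene Nnat (1.28 ± 0.17), Gria2 (1.14), B3galt2 (1.10), the manganese exporter Slc30a10 (1.10) and Agmo (1.02). The largest falls were those of the chemokine Ccl2 (-3.22 ± 0.40), cyclin D1, Ccnd1 (-3.03), the nucleic acid sensor Zbp1 (-2.84), the adhesion molecule Icam1 (-2.72), Tagln2 (-2.60), Tagln (-2.58), Tgfbr2 (-2.37) and Plat (-2.36). Under edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 126 genes were higher and 137 lower (adjusted p between 8.60e-10 for Ccl2 and 0.0134 for Zbp1 among these, each in 3 of 3 libraries). The counts were 28 and 67 with subcluster 4 left out, when Hsd11b1 (0.14, adjusted p = 0.787), Il33, Gria2, Hrh1, B3galt2, Slc30a10 and Agmo lost their calls. They were 44 and 85 with DESeq2, 27 and 52 without replicate 1, 86 and 104 without replicate 2, and 24 and 31 without replicate 3. Hrh1, Slc30a10, Agmo, Icam1, Tagln and Tgfbr2 lost their calls without replicates 1 and 3 (adjusted p from 0.0910 to 0.743), B3galt2 without any replicate (0.175, 0.0597 and 0.138 without replicates 1, 2 and 3), Gria2 and Zbp1 without replicate 1 (0.103 and 0.0695), and Ccl2, Ccnd1 and Tagln2 without replicate 3 (0.0610, 0.271 and 0.157). With doublets kept Ccl2 turned to 0.387, Ccnd1 to 0.733 and Il33 to -0.025.

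Of the 24 astrocyte homeostasis genes 9 were higher in subcluster 3 (17 higher and 1 lower adjusted over the list alone, median 0.50), with the glutamate receptor Grm3 at 0.89 ± 0.18. Of 16 synapse regulators 2 rose and 1 fell (3 and 1, median 0.28), with the growth factor Ptn at 0.88 ± 0.17 and 3064 ± 613 CPM. Of 28 lipid genes 1 rose, Cyp51 of sterol synthesis at 0.74 (10 adjusted over the list alone, median 0.35). Of 70 oxidative phosphorylation genes 2 rose (9 adjusted over the list alone, median 0.32), among them Uqcr11 at 0.63. No mitochondrially encoded gene passed edgeR's test (median 0.22), and mt-Nd3 stood at 0.45 ± 0.17 with an adjusted p of 0.121. In camera the adjusted p came to 2.4e-13 for homeostasis, 0.0316 for synapse regulators, 0.000148 for lipid synthesis, 2.25e-15 for oxidative phosphorylation and 0.0146 for mitochondrially encoded genes, and adjusted p = 0.219, 0.308, 0.366, 0.264 and 0.692 with an estimated correlation. The synapse call was lost without any single replicate (adjusted p = 0.148, 0.0514 and 0.0530 without replicates 1, 2 and 3), the lipid call without replicate 3 (0.0530) and with subcluster 4 left out (0.346), and the mitochondrial call without replicates 2 and 3 (0.234 and 0.165) and with subcluster 4 left out (0.878). Uqcr11 lost its call without each replicate in turn (0.170, 0.147 and 0.0581), Cyp51 without replicates 2 and 3 (0.0793 and 0.950) and Grm3 without replicate 3 (0.347). With doublets kept Cyp51 turned to -0.021.

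Of the lower groups in subcluster 3, 20 of 24 immediate early genes fell (23 adjusted over the list alone, median -1.08), with Ier3 at -1.83 ± 0.22. Of 12 pan-reactive genes 7 fell (9 adjusted over the list alone, median -1.67), with Hspb1 at -1.72 ± 0.18. Of 10 neuroinflammation-type genes 4 fell (5, median -0.83), with C3 at -2.25 in 2 of 3 libraries, and 2 of 4 injury-type genes fell (2, median -1.73), with Tm4sf1 at -1.94. Of 21 interferon genes 10 fell (13, median -0.81), Ifitm3 by 0.95 on the log2 scale. Of 10 MHC class I genes 5 fell (9, median -0.82), H2-T23 by 1.58. Of 10 senescence genes 3 fell (4, median -0.40), Igfbp7 by 1.59. Of 37 chaperones 4 fell (4, median -0.15). Of 12 disease-associated microglia genes 5 fell and 1 rose (5 and 2, median -0.34), Ccl4 by 1.22. By camera the adjusted p was 9.64e-56 for immediate early genes, 2.16e-20 for pan-reactive, 2.81e-10 for neuroinflammation-type and 3.33e-06 for injury-type genes, with adjusted p = 0.0589 for each of these with an estimated correlation. It was 1.88e-16 for interferon, 1.34e-12 for MHC class I, 8.23e-05 for senescence, 3.82e-06 for chaperones and 0.0024 for the microglia list, and adjusted p = 0.0629, 0.0650, 0.175, 0.219 and 0.274 with an estimated correlation. With subcluster 4 left out, the interferon and senescence lists lost their calls (0.122 and 0.851), and without replicate 3 the microglia list (0.259), C3 (0.999), H2-T23 (0.199), Ifitm3 (0.0556) and Ccl4 (0.182) did. With doublets kept the pan-reactive median turned to 0.549 (adjusted p = 0.0238), the interferon median to 0.243 and the senescence median to 0.051. C3 (2.767), Igfbp7 (0.946), Ifitm3 (0.515) and H2-T23 (0.078) turned too. Markers of other classes moved down with these lists: 3 of 6 microglial (5 adjusted over the list alone, median -1.35), 2 of 7 endothelial (-1.14) and all 4 erythrocyte markers (-1.84) fell, as did 1 of 3 pericyte (-1.53, 2 adjusted over the list alone) and 1 of 3 smooth muscle markers (-0.58). From camera the adjusted p was 3.38e-08, 9.54e-05, 5.08e-07, 0.0151 and 0.0141 in that order, and adjusted p = 0.0539, 0.126, 0.130, 0.195 and 0.224 with an estimated correlation. Of the 14 astrocyte markers 8 rose (11 adjusted over the list alone, median 0.62, adjusted p = 4.09e-14, and adjusted p = 0.109 with an estimated correlation).

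The protein degradation lists were not called by camera or fry in subcluster 3. Of the lists camera called there, fry did not pass chaperones (adjusted p = 0.0974), lipid synthesis (0.123), mitochondrially encoded genes (0.275), the microglia list (0.180) or the pericyte (0.185), smooth muscle (0.193) and erythrocyte markers (0.319). No gene of the autophagy (30 genes, median 0.07), proteasome (37 genes, median 0.02 and mean 0.02, with a downward test), lysosomal membrane (30 genes, 0.13), mTOR (31 genes, 0.10, with a downward test), ER chaperone (26 genes, 0.07), secretory (42 genes, 0.11) or ribosomal lists (78 genes, -0.02 against a mean of 0.01) passed edgeR's test, in which 958 of all genes had an unadjusted p under 0.05. Their adjusted p in camera was 0.974, 0.878, 0.0932, 0.974, 0.946, 0.523 and 0.670. Of 34 hydrolases 3 fell (3 lower and 1 higher adjusted over the list alone, median 0.11 against a mean of -0.04, adjusted p = 0.777). Of 33 ubiquitin genes 1 fell (the same, median 0.01 against a mean of -0.03, 0.521). Of 16 phagocytic genes 2 rose (2 and 1 lower, 0.217). Of 18 glycolysis genes 1 rose (2 and 1 lower, 0.163). Gfap (-0.03), Sqstm1 (-0.33), Map1lc3b (0.11), Lamp1 (0.13), Lamp2 (0.17), Ctsd (-0.32) and Mtor (0.47) did not pass, with adjusted p from 0.310 to 0.987 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

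Subcluster 4, with 15 cells of replicate 1 and 40 of replicate 3, had its largest rises in Lcn2 and C3. Lcn2 (ENSMUSG00000026822.14, chromosome 2, 32384633 to 32388252) was higher by 6.20 ± 0.26 (log2 ± SE), with 772.6 CPM in replicate 1 and 8335 CPM in replicate 3, against 137.3 CPM in the other subclusters. The SE rests on the pooled spread and does not show how far these libraries differed. Complement C3 (ENSMUSG00000024164.15, chromosome 17, 57203970 to 57228136) was higher by 5.79 ± 0.24, with 511 CPM and 2306 CPM against 22.5 CPM. The ferroxidase Cp (5.42), Steap4 (5.30), the chemokines Cxcl1 (5.04) and Ccl2 (4.75), the antiviral gene Rsad2 (4.78) and Ccnd1 (4.46) followed, and Gfap was higher by 1.13 ± 0.20. Among the falls, Kirrel3, Lss, Hrh1, Ctla2a and Kcnt1 had no UMI and were at least 4.10, 4.53, 4.045, 4.85 and 5.40-fold lower, and Hsd11b1 changed by -3.81 ± 0.37 and Hba-a2 by -3.52. Using edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 468 genes were higher and 316 lower (adjusted p = 9.22e-43 for Lcn2 and C3 and 5.20e-06 for Gfap, in 2 of 2 libraries), with 225 and 143 without replicate 1, and 155 and 73 without replicate 3. Leaving out either of those leaves a single profile of this subcluster, which is assumed to vary like the others. Without replicate 1 and without replicate 3, Lss, Hrh1, Ctla2a and Kcnt1 lost their calls (adjusted p from 0.252 to 0.564), as did Gfap without replicate 1 (0.38, adjusted p = 0.689) and Hba-a2 without replicate 3 (-0.70, adjusted p = 0.866). Ctla2a turned to 1.552 with the second seed for the UMI split (adjusted p = 0.00364) and to 1.808 at Leiden resolution 0.2 (adjusted p = 0.00548).

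**Figure D3:**
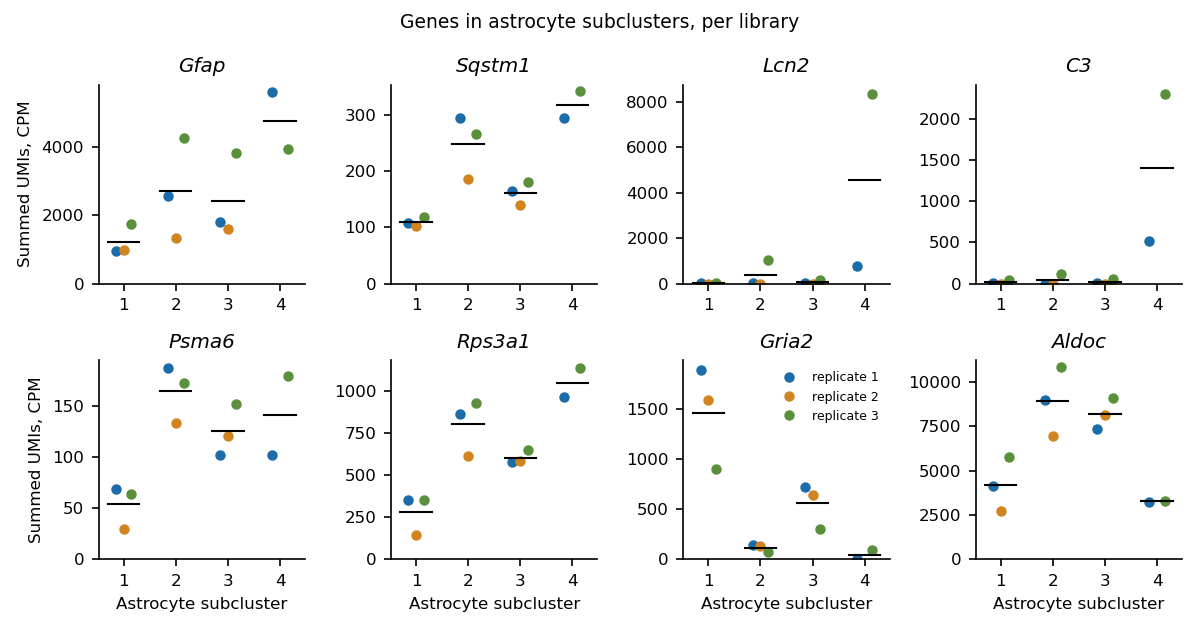
Summed UMIs of 8 genes as CPM (vertical axes) in astrocyte subclusters 1 to 4 (horizontal axes), 1 point per library and a line at the mean over libraries. Lcn2 reaches 8335 CPM and C3 2306 CPM in subcluster 4 of replicate 3, and Rps3a1 has its lowest mean, 283 CPM, in subcluster 1.

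Of the 12 pan-reactive genes 10 were higher in subcluster 4 (the same adjusted over the list alone, median 2.90), as were 7 of 10 neuroinflammation-type genes (the same, median 2.41), 2 of 4 injury-type genes (the same, median 1.83, with Tm4sf1 at 2.24), 17 of 21 interferon genes (the same, median 2.24) and 8 of 10 MHC class I genes (the same, median 1.51), with H2-T23 at 3.08 ± 0.25. All 24 immediate early genes rose (the same, median 1.86), with the transcription factor Egr1 at 2.76 ± 0.21, 4 of 10 senescence genes rose (the same, median 0.85), with Igfbp7 at 3.57, 49 of 78 ribosomal protein genes rose (64 adjusted over the list alone, median 0.62), with Rps4x at 1.01, and 8 of 37 chaperones rose (9 higher and 1 lower adjusted over the list alone, median 0.44), with Cryab at 1.38. With camera the adjusted p for pan-reactive genes was 5.3e-27, and adjusted p = 0.00803 with an estimated correlation, so this call held. It was 4.03e-15 for neuroinflammation-type, 0.00177 for injury-type, 5.25e-26 for interferon, 4.72e-13 for MHC class I, 1.74e-41 for immediate early, 3.67e-06 for senescence, 7.29e-25 for ribosomal and 0.00043 for chaperone genes. These did not hold: adjusted p = 0.0589, 0.128, 0.0629, 0.126, 0.0589, 0.0629, 0.251 and 0.132 with an estimated correlation, in that order. The chaperone list lost its call without replicate 1 (adjusted p = 0.191), Rps4x too (0.101), and H2-T23 without replicate 3 (0.120).

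Lower in subcluster 4 were 13 of 24 astrocyte homeostasis genes (15 adjusted over the list alone, median -0.77), 9 of 28 lipid synthesis genes (10 adjusted over the list alone, median -0.49), with Mvd at 2 UMIs, 3 of 13 mitochondrially encoded genes (4 adjusted over the list alone, median -0.36), with mt-Nd6 at -1.37, and 2 of 16 phagocytic genes, with 1 higher (the same, median -0.35), the bridging protein Mfge8 among them at -1.68 ± 0.23. Camera gave an adjusted p of 5.12e-11, 2.28e-05, 0.0018 and 0.0337, and adjusted p = 0.273, 0.368, 0.592 and 0.245 with an estimated correlation. The lipid list and Mvd and mt-Nd6 lost their calls without replicate 3 (adjusted p = 0.358, 0.570 and 0.713), and the mitochondrial and phagocytic lists without replicate 1 (0.0613 and 0.382). Markers of astrocytes were lower too (10 of 14, median -1.08, adjusted p = 5.75e-12, and adjusted p = 0.130 with an estimated correlation), as were 3 of 6 microglial (-1.37, adjusted p = 0.00258), 2 of 7 endothelial (-1.43, 0.0221) and all 4 erythrocyte markers (-3.41, 0.000261), with adjusted p = 0.109, 0.224 and 0.224 with an estimated correlation.

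The protein degradation lists were not called by camera in subcluster 4 either, though the proteasome passed with fry (adjusted p = 0.0328). Of the lists camera called there, fry did not pass lipid synthesis (0.130), mitochondrially encoded genes (0.199) or the endothelial (0.0523) and erythrocyte markers (0.278). Of 37 proteasome genes 3 rose (the same adjusted over the list alone, median 0.31, adjusted p = 0.0616). Of 30 autophagy genes 2 rose (the same, 0.946). Of 30 lysosomal membrane genes 1 rose (the same, median 0.05 against a mean of -0.02, 0.946). Of 33 ubiquitin genes 3 rose (2 adjusted over the list alone, 0.2998). Of 26 ER chaperones 3 rose (the same, 0.2998). Of 42 secretory genes 3 rose (1 adjusted over the list alone, 0.327). Of 31 mTOR genes 1 rose (the same, 0.710), while 1 of 34 hydrolases fell (the same, median 0.10 with a downward test, 0.746). Of 16 synapse regulators 3 rose and 2 fell (4 and 3 adjusted over the list alone, median -0.18 against a mean of 0.16, 0.836). Of 12 disease-associated microglia genes 3 rose and 2 fell (3 and 4, 0.836). Of 18 glycolysis genes 1 rose and 2 fell (3 and 3, 0.946). Of 70 oxidative phosphorylation genes 1 fell (none, 0.307). Sqstm1 was higher by 0.88 ± 0.20 in 2 of 2 libraries (adjusted p = 0.000576 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 0.426 without replicate 3). Map1lc3b (0.08), Lamp1 (0.19), Lamp2 (0.28), Ctsd (0.08) and Mtor (-0.50) did not pass, with adjusted p from 0.501 to 0.890.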

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

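The tests of depth, of microglial markers, of the origin of subcluster 4 by library and of microglial and endothelial free RNA were chosen only after the result was seen. Cells of unnamed clusters took no part in the comparisons, and some held a gene in a higher share of cells than endothelial cells did. Lcn2 had a UMI in 86.7% (104 of 120 cells, exact 95% interval 79.3 to 92.2) of cluster 22 in replicate 3, against 15.9% of endothelial cells, at median depths of 819.5 and 6275 UMIs, and in 3 of 8 and 1 of 2 cells of that cluster in replicates 1 and 2. S100a9, a neutrophil gene, had a UMI in 31.8% (14 of 44 cells, 18.6 to 47.6) of cluster 25 in replicate 1 and in 5.71% (2 of 35 cells, 0.700 to 19.2) in replicate 3, against 0.265% and 0 of 1639 endothelial cells. Nkg7, a gene of cytotoxic lymphocytes, had a UMI in 36.4% (16 of 44 cells) of cluster 25 in replicate 1 and in 65.7% (23 of 35 cells) in replicate 3, against 0.133% and 0.244% of endothelial cells. The median depth of cluster 25 was 3470.5 and 3250 UMIs, against 7467 and 6275 in endothelial cells. Lcn2 was among the 10 leading genes of cluster 22, whose closest class was astrocyte, and S100a9 and Nkg7 among those of cluster 25, so their shares restate in part how the clusters were formed.

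The lower proteasome, ribosomal and respiratory RNA of subcluster 1, with its higher RNA of long genes, was weighed first. Among cells of 2000 to 20000 UMIs the proteasome median stayed at -0.461 (camera adjusted p = 0.00164), though it had been -0.735 before. That range did not match depth, so it cannot argue against depth as the cause. Medians within it were 3734.5, 3923 and 4235 UMIs in replicates 1, 2 and 3 of subcluster 1. In subcluster 3 they were 8208, 9710 and 12355 UMIs. Subcluster 2 was shallower, with a median of 959.5 UMIs over all its cells, and its proteasome list was higher. Droplets rich in nuclear RNA and poor in cytoplasm are a candidate explanation that stays open: an unnamed cluster closest to microglia, low in UMIs, had a proteasome median of -0.751 against named microglia (-1.18 to -0.345 over the 3 libraries), and genes of long span in subcluster 1 lay 0.621 (log2) above short ones matched on level (0.610 to 0.631 over libraries, with spans known for 6780 of 6829 genes). A lower proteasome level in whole cells is not separated from this by any test here. With 1 group in the design, no biological explanation was tested for this or the patterns that follow.

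In the reported clustering the inflammatory subcluster 4 came mostly from replicate 3. With list genes kept its counterpart (Jaccard index 0.293) did not, with 99, 3 and 68 cells in replicates 1, 2 and 3. Other counterparts came mostly from replicate 3, with 53, 3 and 98 for all UMIs and 56, 5 and 77 at Leiden resolution 0.8. They had 12, 0 and 82 cells with z-scores over all libraries and 34, 1 and 62 with the second seed. At Leiden resolution 0.2 they had 18, 3 and 51, and with the stricter cell filter 11, 1 and 23. For microglial RNA in the same droplets, 6 microglial markers had a median of -1.37 (-2.06 to -0.216), so their share was not raised in subcluster 4. The compared mean includes subcluster 2, where these markers were higher at a median depth of 959.5 UMIs, against 20275 in subcluster 4. Marker UMIs per cell were not compared for subcluster 4, so some microglial RNA there is not excluded. A response to the dissociation may contribute, as in cells of subclusters 1 to 3 the pan-reactive share was higher by 0.795 (log2, 0.443 to 1.39 over libraries) in the cells richest in immediate early RNA than in the poorest. Pan-reactive UMIs in those cells were 3.02, 4.92 and 11.5 per 10000 in replicates 1, 2 and 3, below the 22.8 and 114 of subcluster 4 in replicates 1 and 3. A state of the animals and an effect of the preparation cannot be told apart, since in the reported clustering 72.7% of its cells (40 of 55) came from replicate 3, which gave 33.5% of the astrocytes, and the labels do not part animals from preparation.

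The haemoglobin, microglial and endothelial RNA of subcluster 2 was weighed last. Free RNA in droplets of low depth is a candidate explanation for the microglial and endothelial part, where UMIs per cell in subcluster 2 were 0.650 of those in subcluster 3 (0.507 to 0.768) while total UMIs were 0.0939 to 0.136 of them. For haemoglobin the ratio was 4.27 (0.732 to 10.97 over libraries) and stays open, because 5 cells of replicate 3 held 90.5% of the haemoglobin UMIs of subcluster 2 there. The ratio was 1.102 and 0.732 in replicates 1 and 2, near the 1 that free RNA predicts, and the median cell held 1, 4 and 3 haemoglobin UMIs in subcluster 2 of replicates 1, 2 and 3 and 0, 5 and 3 in subcluster 3.

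Of the 46 choices of 1 profile per library as the compared level, only the real one (1 of 46) called as many genes as subcluster 1 (1130 genes, highest other 156). Its profiles thus stood apart more alike across libraries than the other choices, which all mixed profiles of different subclusters. Because of that mixing the comparison does not by itself exclude chance. For subcluster 2 this comparison does not settle it: 4 of 46 choices called as many (74 genes, highest other 156), and the highest took profiles of subclusters 4, 2 and 4, so it points to structure of the profiles. For subcluster 3 the comparison was no test: the real choice called 0 genes, so all 46 of the 46 choices counted as many, while the full edgeR fit called 126 higher and 137 lower (958 at an unadjusted p under 0.05). For astrocytes against other classes 1 of 40 choices called as many (1258 genes, highest other 475), but the same UMIs had formed the classes, so this was no test of chance. These choices used a model of 2 levels that treats all other profiles as 1 group, which makes its counts smaller than those of the full fit. Subcluster 4, in 2 libraries, had no such test.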

How the results depend on the processing

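Alternatives of 2000 to 20000 UMIs, at least 2000 UMIs, subcluster 4 left out and no erythrocyte class were chosen after seeing the data. The others were fixed before. Of 228 counts, 152 moved by less than 1.5 times and 76 by more. Of 966 values of called gene lists, 764 kept the direction of the test and the call, 193 lost the call and 9 reversed in that direction. Of 2421 values of named genes 2043 kept direction and call, 310 lost the call, 20 gained it and 48 reversed. With an estimated correlation 0 of the 16 camera calls held in the class comparison, 0 of 13 in subcluster 1, 0 of 9 in subcluster 2, 0 of 14 in subcluster 3 and 1 of 13 in subcluster 4, the pan-reactive list. For the proteasome in astrocyte subcluster 1, its list stayed negative and called in each other alternative run for it, from -0.244 at Leiden resolution 0.2 to -0.949 with all UMIs for clustering and testing. Where values below changed, the cause was not tested, except that alternatives with fewer cells or libraries have fewer UMIs.

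The replicate block carried part of the calls. With no replicate block subcluster 2 had 79 higher and 179 lower genes, subcluster 3 had 8 and 26, and subcluster 4 had 181 lower. With DESeq2, subcluster 1 had 734 lower genes, subcluster 2 had 220 higher, subcluster 3 had 44 higher and 85 lower and subcluster 4 had 190 lower. With no low-count filter subcluster 2 had 209 higher genes, and the median of all genes was 0.24, -0.291 and 0.139 in subclusters 1, 2 and 3.

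The stricter cell filter left 623 higher and 428 lower genes in subcluster 1, 110 and 84 in subcluster 2, 35 and 73 in subcluster 3 and 250 and 130 in subcluster 4, with an astrocyte share of 7.84%. Under it Cxcl5 (0.462) and Ctsd (0.434) reversed in subcluster 1. Gfap (-0.223), Ctsd (-0.011) and the homeostasis list (-0.291) did so in subcluster 2, Gfap (0.207) and Lamp2 (-0.166) in subcluster 3, and Lamp1 (-0.044) in subcluster 4. Cells with 2000 to 20000 UMIs gave 722 and 480 genes in subcluster 1, 57 and 118 in subcluster 2, 45 and 38 in subcluster 3 and 211 and 191 in subcluster 4. There Ctsd reversed in subcluster 2 (-0.103), Map1lc3b (-0.053) and Lamp1 (-0.025) in subcluster 3, and Map1lc3b (-0.072) and Lamp1 (-0.031) in subcluster 4.

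With all UMIs for clustering and testing, subcluster 1 had 2432 higher and 2263 lower genes and 7 gene lists called, subcluster 2 had 1275 and 1038 genes, and subcluster 4 had 940 and 497. Lamp2 (-0.213) and the immediate early list (0.335) reversed in subcluster 1, and Map1lc3b (-0.029) and Mtor (-0.092) in subcluster 3. With list genes kept in clustering, 8 gene lists were called in subcluster 1, 732 genes were lower in subcluster 2 and 77 in subcluster 4. Gfap reversed in subcluster 3 (0.277), and Ctsd (-0.234) and Mtor (0.065) in subcluster 4. With the second seed for the UMI split Lamp2 reversed in subcluster 1 (-0.245), Map1lc3b (-0.028) and Mtor (-0.022) in subcluster 3, and Ctla2a in subcluster 4 (1.552). With z-scores over all libraries Lamp2 reversed in subcluster 3 (-0.053). With no low-count filter Gfap reversed in subcluster 3 (0.081), and Map1lc3b (-0.037) and Ctsd (-0.046) in subcluster 4.

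At Leiden resolution 0.2, subcluster 1 had 690 higher and 370 lower genes, subcluster 2 had 97 and 230 and subcluster 4 had 256 higher, and subcluster 3 had no counterpart. Gfap reversed in subcluster 2 (-0.048), and Ctla2a (1.808) and Map1lc3b (-0.167) in subcluster 4. At Leiden resolution 0.8, 7 gene lists were called in subcluster 1, and subcluster 2 had 100 and 103 genes and subcluster 4 had 282 and 197. The immediate early list reversed in subcluster 1 (0.302), Gfap (-0.003) and the homeostasis list (-0.021) in subcluster 2, Map1lc3b (-0.128) in subcluster 3 and Ctsd (-0.241) in subcluster 4.

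With subcluster 4 left out of the fit, 7 gene lists were called in subcluster 1, and subcluster 2 had 861 and 930 genes and subcluster 3 had 28 and 67. The immediate early list reversed in subcluster 1 (0.215), the homeostasis list in subcluster 2 (-0.176) and Gfap in subcluster 3 (0.314). With doublets kept, subcluster 3 had 216 and 330 genes, subcluster 4 had no counterpart, and the pericyte share was 0.579%, where a cluster of 308 cells closest to pericytes stayed unnamed. Ccl4 (-0.034) and Ctsd (-0.504) reversed in subcluster 2. In subcluster 3 so did Il33 (-0.025), Ccl2 (0.387), Ccnd1 (0.733), C3 (2.767), H2-T23 (0.078), Cyp51 (-0.021), Ifitm3 (0.515), Igfbp7 (0.946), Gfap (0.614) and the pan-reactive (0.549), interferon (0.243) and senescence lists (0.051).

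With each replicate left out in turn, the class comparison had 3250 to 4252 higher and 1897 to 3460 lower genes and 15 to 18 lists called. Subcluster 1 had 682 to 1589 and 558 to 1416 genes and 9 to 13 lists, subcluster 2 had 51 to 500 and 89 to 397 genes and 8 lists, subcluster 3 had 24 to 86 and 31 to 104 genes and 10 to 13 lists, and subcluster 4 had 155 to 489 and 73 to 325 genes and 10 to 13 lists. The lowest counts came without replicate 1 or replicate 3, which held most of the cells. The astrocyte share ran from 15.99% to 21.87%. Gfap ran from -0.131 (without replicate 3) to 0.363 in subcluster 2 and from -0.281 (without replicate 3) to 0.28 (without replicate 1) in astrocyte subcluster 3. In subcluster 4 Lamp2 ran from -0.146 (without replicate 3) to 0.53 and Ctsd from -0.169 (without replicate 1) to 0.441.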

Other observations

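Microglia, which the comparisons used only as a reference class, fell into several clusters. A cluster led by Cd83, Tnf and Osm, genes of activated microglia, held 32.1% ± 0.610 (SD, n = 3) of the microglia of a library, and another led by the cytokine genes Il1a, Ccl3 and Il1b held 28.2% ± 7.61. A cluster led by the homeostatic genes P2ry12 and Tmem119 held 16.4% ± 4.44, and a shallow cluster with a median of 1716 UMIs held 15.2% ± 8.76. A cluster led by Spp1, Cst7, Lpl and Gpnmb, genes of disease-associated microglia, held 8.04% ± 6.44, with 94, 1 and 106 cells in replicates 1, 2 and 3. Ependymal cells fell into a deep and a shallow cluster of like size, with 48.7% and 51.2% ± 3.82 of the class and medians of 10768.5 and 1013 UMIs.

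Immediate early RNA took 4.88% ± 0.659 of endothelial UMIs and 0.352% ± 0.0825 of astrocyte UMIs (SD, n = 3). Ubiquitin genes took 1.29% of endothelial and 0.522% ± 0.0178 of astrocyte UMIs, and ER chaperone genes 0.624% of microglial and 0.257% ± 0.00639 of astrocyte UMIs.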
